A study of Arabidopsis thaliana with 4 samples.

How the data were processed

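Root RNA of Arabidopsis thaliana was measured on 4 Affymetrix Arabidopsis Gene 1.0 ST arrays, 1 for each of 4 genotypes: wild type (WT, accession Columbia) and plants labelled CEPD1ox, CEPD2ox and CEPDL2ox, names that mark overexpression of a gene of the CEPD family. Per the labels, plants were grown at 22 °C in continuous light, moved after 7 d to a nitrogen-replete medium with 10 mM NH4Cl and 10 mM KNO3, and harvested at 14 d; 100 ng of total RNA was labelled per array. The labels give 1 array per group, so there were no replicates, no spread within a group and no test. Differences were therefore not checked by replication, and no p-value across genes is given, since genes are not replicates. The number of arrays limits the precision of every value.

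The deposited values are log2 signals per row of the array (transcript cluster), made with Affymetrix Expression Console 1.3, per the submitters' processing notes. The summarization and normalization methods are not given in the sources used here. The base of the logarithm was inferred from the values, which run from 0.431 to 13.8, within the range of a 16-bit scanner on a log2 scale. The median over all rows was 5.16 for WT, 5.11 for CEPD1ox, 5.13 for CEPD2ox and 5.18 for CEPDL2ox. Values were used as deposited. A fold is 2 raised to the difference of log2 signals, and array signals near background understate the difference in RNA.

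The table holds 38408 rows. The annotation of the array platform named 1 gene for 16722 rows, several genes for 759 and none for 20927; rows of the latter kinds were given no gene name. Of the rows with 1 gene, 16574 matched a locus of the TAIR10.1 gene table and 148 did not and kept the annotation's name. The table was used only for names. No genome build is given in the sources used here, so no coordinates are reported. NRT2.1 and NRT3.1, the transporter and its partner protein named in the plan, had no row with a name of their own and were not analysed here. The names CEPD1, CEPD2, CEPDL1, CEPDL2 and CEPH come from knowledge of the loci, not from these tables. Where a gene had several rows (148 genes), the row with the highest mean signal was taken. This gave 16548 genes. Genes whose highest value on the 4 arrays was below 2.78, the 25th percentile of all gene values, were left out (3316 genes), which kept 13232.

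For each line, genes at least 2-fold higher or lower than the WT array were counted. Genes past 2-fold in the same direction in all 3 lines were counted too. Since the 3 comparisons share the WT array, these counts were set beside 1000 simulated sets of 4 unchanged arrays, drawn from the deviations of the lines from their mean in 20 bins of expression, and beside the overlap that independent lists of the same sizes give. The same count was made with each other array taken as the one that stands apart. On simulated data with 200 genes changed in all 3 lines, the count recovered 88.4% of those changed by 1.5 on the log2 scale, 98.4% of those changed by 2 and 99.95% of those changed by 3, among 13232 genes. It also called on average 15.5, 17.1 and 16.9 unchanged genes in these sets. The changes were added in full at every signal level with no background limit, so the shares recovered may be too high for genes with low signals.

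Before the data were examined, the groups, comparisons, thresholds, filter, alternatives, rule for named genes and 32 gene lists with 431 members were fixed. The rule named the CEPD family, CEPH, NRT2.1 and NRT3.1. It also named the 12 genes with the largest smallest-of-3 log2 ratio in each direction and, per line, the 3 genes furthest in each direction from the mean of the other lines among those past 2-fold from both, leaving out the overexpressed genes. Last, it named up to 4 members of each list with the largest mean ratio. For 9 members the TAIR10.1 table gave the symbol to another locus, and they were left out. Of the rest, 75 had a named row and 61 passed the filter. For lists with at least 3 such members, a minimum set after the data were seen, the median of the members' mean log2 ratio was ranked among 10000 random lists of the same size and matched expression. A list was said to stand apart below the 2.5th or above the 97.5th percentile. This percentile ranks genes within the same arrays and holds no spread between arrays or plants. It therefore does not weigh whether a list would differ again on other arrays.

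Alternatives were thresholds of 1.5-fold and 3-fold, no filter and a filter at the median, shifting the arrays to the same median, quantile and cyclic loess normalization, the mean over the rows of a gene, leaving out each line, and, for lists, the mean over members and unmatched random lists. Counts over all rows, and lists without the overexpressed genes and CEPH, were added after the data were seen. A planned change of pseudocount applied to linear values only and was not run. Computations used R 4.3.3 with limma 3.58.1 for the normalizations, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.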

Results

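Root transcript levels were compared between WT plants and 3 lines labelled as overexpressing CEPD family genes, with 1 array per genotype and no replicates. CEPD1, CEPD2 and CEPDL2 are small glutaredoxin-like polypeptides of class III, known as mobile signals that report nitrogen demand from shoot to root. The study's title concerns a type 2C protein phosphatase that dephosphorylates the nitrate transporter NRT2.1. The comparison therefore asks which root transcripts, the phosphatase gene among them, differ from WT in these lines on nitrogen-replete medium. The 4 arrays were alike as a whole. Across all rows, Pearson's r between arrays lay between 0.983 and 0.984, over rows that are not independent replicates. Across the 13232 genes kept, the SD of the log2 difference between 2 arrays lay between 0.305 and 0.333.

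CEPD2 was 225-fold higher in CEPD2ox than in WT, with a log2 signal of 9.22 against 1.41, which is below the filter value of 2.78, so this fold is set against a signal near background. CEPDL2 was 4.11-fold higher in CEPDL2ox, at 5.49 against 3.46. In the lines that do not overexpress them, CEPD2 and CEPDL2 lay between -0.15 and 0.06 of WT on the log2 scale. CEPD1 (AT1G06830) did not follow this pattern. Its signal was 3.04 on the array labelled CEPD1ox and 2.66 on the WT array, a difference of 0.38, with differences of -0.47 in CEPD2ox and -0.32 in CEPDL2ox. The signals of CEPD1 in WT, CEPD2ox and CEPDL2ox lay below the filter value, so these differences are limited by background. Overexpression of CEPD1 was thus not seen on the array labelled CEPD1ox, and each direction drawn from that array below carries this limit. Where the probes of this row lie relative to the introduced sequence was not analysed here. CEPDL1, the fourth member of the family, stayed below the filter on all 4 arrays.

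**Figure D1:**
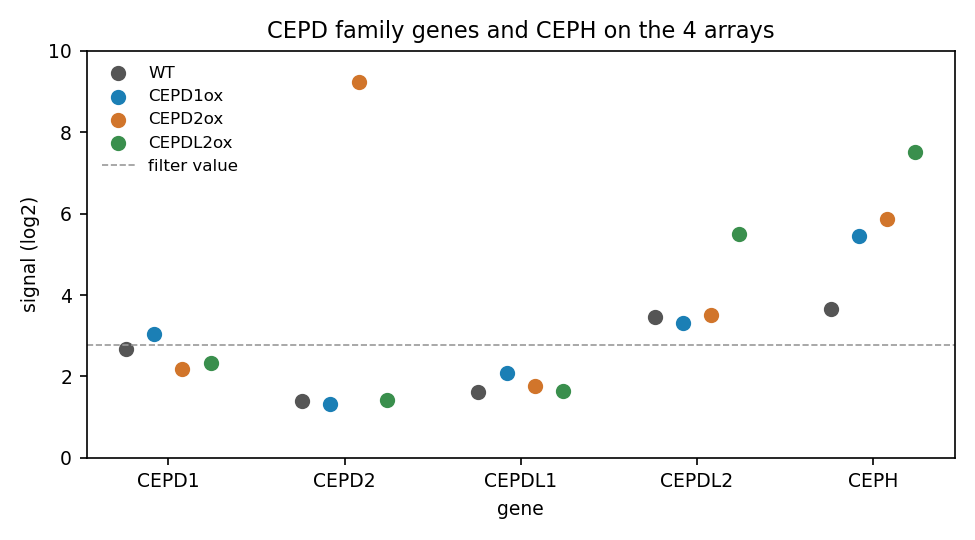
Log2 signal (vertical axis) of the CEPD family genes and CEPH (horizontal axis), with 1 point per array and the filter value of 2.78 as a dashed line. CEPD2 reaches 9.22 in CEPD2ox and CEPDL2 5.49 in CEPDL2ox, CEPD1 stays at 3.04 on the array labelled CEPD1ox, and CEPH is higher in the 3 lines than in WT.

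CEPH (AT4G32950), a type 2C protein phosphatase gene, was higher than WT in all 3 lines. Its log2 signal was 3.67 in WT, 5.45 on the array labelled CEPD1ox, 5.87 in CEPD2ox and 7.51 in CEPDL2ox. These are 3.44-, 4.62- and 14.3-fold differences, with a mean log2 ratio of 2.61 ± 1.09 (SD over the 3 lines, which share 1 WT array). Here and below, such an SD is only the spread of the line signals. It leaves out the error of the single WT value, so a small SD does not make a difference from WT precise. CEPH was put in the plan because the study's title concerns such a phosphatase, so its choice may not be independent of these arrays. By the smallest of its 3 ratios, 1.78, CEPH ranked 2 among the kept genes other than the overexpressed ones. With another array taken as the one apart, 1 gene reached this size among 39687 pairs of gene and array, over genes of all levels. This was AT2G30670 on the CEPDL2ox array, a gene that was also at least 2-fold higher than WT in all 3 lines. CEPH's own SD between the lines, 1.09, exceeded the 95th percentile of 0.35 among genes with a mean signal of 5 to 7. CEPH was also 3.59-fold higher in CEPDL2ox than the mean of the other lines. Of high-affinity nitrate transport, only NRT2.5 had a named row, and it lay below the filter. NRT2.1 and NRT3.1 were not analysed here.

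Compared with WT, the array labelled CEPD1ox had 97 genes at least 2-fold higher and 63 lower, 1.21% of the genes kept. CEPD2ox had 67 higher and 52 lower, 0.90%, and CEPDL2ox had 102 higher and 65 lower, 1.26%. Most of these genes had low signals. Leaving out the overexpressed genes, only 2, 0 and 7 of them had a mean log2 signal of 7 or above over the lines, out of 3939 such genes. The median SD between the lines was 0.28 for genes with a mean signal below 3 and 0.09 for those at 7 or above. Requiring a signal above the median lowered the totals from 160 to 34, from 119 to 25 and from 167 to 52 genes.

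Beside CEPH, 8 genes were at least 2-fold higher in all 3 lines. AT1G49570, a class III peroxidase gene, was 3.63-, 4.36- and 5.55-fold higher in the array labelled CEPD1ox, CEPD2ox and CEPDL2ox, with a mean log2 ratio of 2.15 ± 0.31. GLR2.2, a glutamate receptor-like channel gene, had a mean ratio of 1.91 ± 0.18, and AT2G30670, a tropinone reductase-like gene, one of 2.07 ± 1.14. AT1G60130, a jacalin-related lectin gene, had a mean ratio of 1.66 ± 0.41. The others were AT3G32400, AT3G49820, AT1G59171 and AT4G01516, with mean ratios between 1.16 and 1.42. The WT signals of AT1G60130, AT3G32400 and AT4G01516 lay below the filter value, so their ratios are set against a level near background. AT4G01516 also lay below it on the array labelled CEPD1ox (2.47) and in CEPDL2ox (2.68). AT2G30660, AT2G30310 and AT5G12960 followed, each short of 2-fold in at least 1 line, with smallest ratios of 0.98, 0.97 and 0.95, and the latter pair was below the filter value in WT too.

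Lower than WT in all 3 lines by at least 2-fold were 9 genes. AT3G22142, of the lipid-transfer and 2S albumin superfamily, differed most by its mean, at -2.49 ± 0.67, and had a signal of 8.71 in WT. AT3G62510, related to protein disulfide isomerases, had a mean ratio of -1.83 ± 0.09. AT3G15356, a legume lectin-like gene, had one of -1.59 ± 0.17, and AT1G64710, an alcohol dehydrogenase-like gene, one of -1.50 ± 0.14. The cytochrome P450 gene AT3G44970 had a mean ratio of -1.82 ± 0.53, and the methyltransferase gene AT1G15125 one of -1.56 ± 0.42. PRK, the phosphoribulokinase of the Calvin cycle, was at -1.68 ± 0.40, from a WT signal of 4.58. The remaining genes, AT5G28810 and AT4G14358, had mean ratios of -1.76 and -1.21. AT5G52090, AT1G23510 and AT5G44400, a berberine bridge enzyme-like gene, came next with ratios nearest to WT of -0.98, -0.91 and -0.88. In all 3 lines AT1G64710, AT4G14358, AT5G52090 and AT1G23510 lay below the filter value, and AT3G44970, PRK and AT5G28810 did so in at least 1, so the sizes of these ratios are limited by background.

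**Figure D2:**
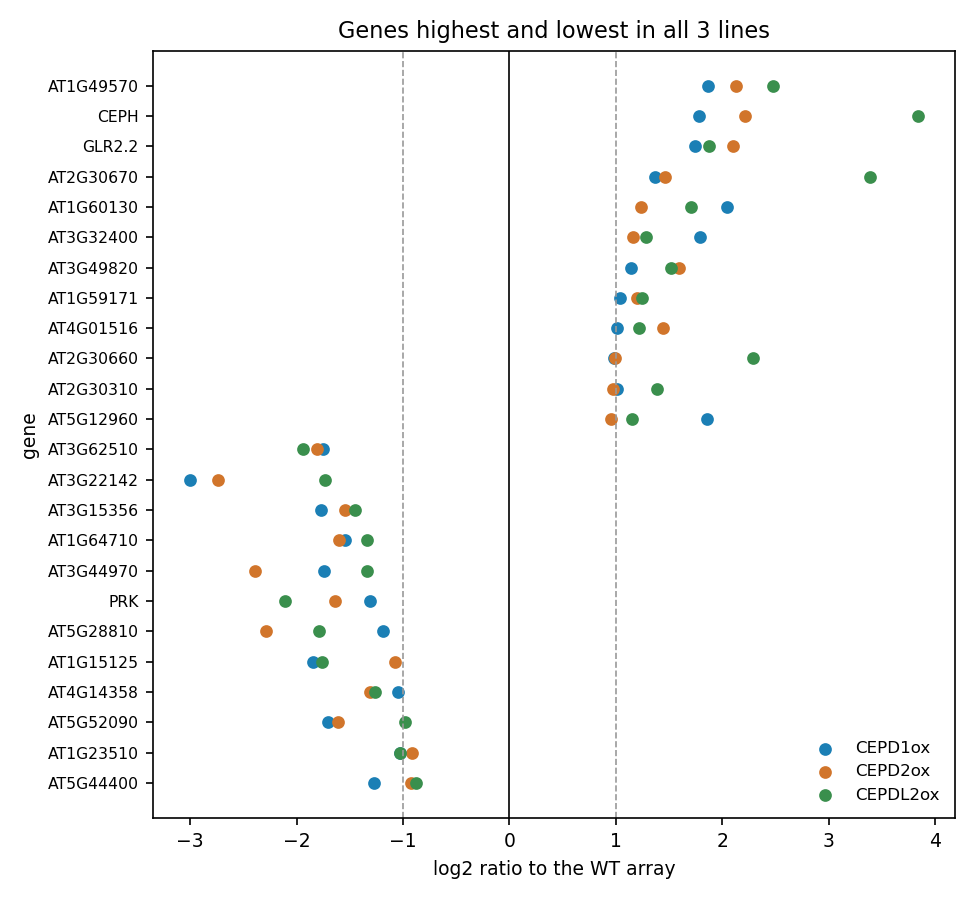
Log2 ratio to the WT array (horizontal axis) of the 12 genes highest and the 12 lowest in all 3 lines (vertical axis), with 1 point per line and dashed lines at 2-fold. CEPH spreads from 1.78 to 3.84 between the lines and AT3G62510 from -1.93 to -1.75.

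The number of these genes lay within the range that simulated unchanged arrays gave. The spread of the simulated arrays was drawn from lines that overexpress different genes, so it can hold differences between the lines and widen this range. The 9 genes higher in all 3 lines compare with a median of 8 in simulated unchanged arrays that share a WT array (3 to 14 in the central 95% of sets). The 9 lower compare with a median of 9 (4 to 15). Independent lists of the same sizes would share 0.0038 and 0.0012 genes, a value that leaves out the shared WT array. With each array taken as the one apart, 18 genes stood apart on the WT array, 21 on the array labelled CEPD1ox, 19 on CEPD2ox and 21 on CEPDL2ox. Without the overexpressed genes these numbers were 18, 21, 18 and 20. Those for the line arrays can hold effects of the overexpressed genes, so they do not measure the spread between unchanged arrays alone. With only 1 WT array its part could not be removed by splitting the controls. With 1 line fewer required, 18 genes were higher without the array labelled CEPD1ox, 20 without CEPD2ox and 17 without CEPDL2ox, and in the same order 13, 14 and 15 were lower. With a filter at the median, 4 genes were higher and 3 lower in all 3 lines, and the arrays stood apart in 7, 3, 8 and 10 genes. Across 13229 genes, the ratios of the lines correlated at r = 0.46, 0.52 and 0.44. Unchanged simulated arrays gave 0.50, a value that their equal spread and the shared WT array fix in advance. The covariances of the line ratios, 0.043, 0.052 and 0.042, differed from the simulated 0.051 by -0.0079, 0.0014 and -0.0085.

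**Figure D3:**
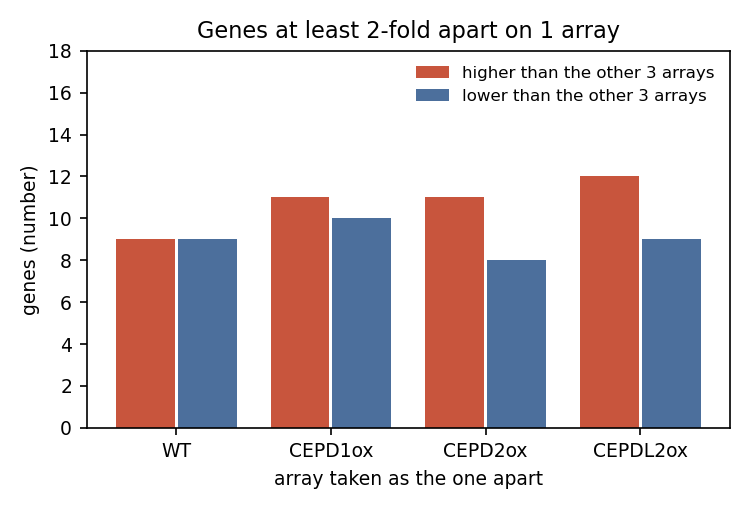
Number of genes (vertical axis, from 0) at least 2-fold higher or lower on 1 array than on each of the other 3, for each array in turn (horizontal axis), overexpressed genes included. The WT array has 9 and 9 genes, and the line arrays have between 8 and 12 in each direction.

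Of the gene lists, 7 had at least 3 members past the filter, and 4 of these stood apart in the mean of the 3 lines against WT. With the array labelled CEPD1ox, CEPD2ox or CEPDL2ox set against the rest, 2, 3 and 3 lists did so. The CEPD family was among these for the array labelled CEPD1ox and for CEPD2ox. The CEPD family did so by construction, since it holds the overexpressed genes (percentile 99.6, against 52.5 without CEPD2ox and 33.3 without CEPDL2ox, where its median turned from 0.65 to -0.05). In what follows on lists, members are counted by the sign of their ratio in every line, whatever its size. The other class III glutaredoxins had a median log2 ratio of 0.30 over 11 members (percentile 99.4), and 5 members had a ratio above 0 in every line and 0 had one below 0. ROXY2 was 2.18-fold higher by its mean ratio (SD of the log2 ratio 0.39). ROXY14 had a mean log2 ratio of 0.97 ± 0.08, ROXY19 one of 0.61 ± 0.31 and ROXY20 one of 0.44 ± 0.53, and no member passed 2-fold in all 3 lines. The WT signals of ROXY2, ROXY14 and ROXY19 lay between 2.06 and 2.46, below the filter value, so that these genes were kept for their signals in the lines and their ratios are set against a level near background. These genes are close paralogs, and probes shared between them were not examined. The list's percentile was 95.2 without CEPDL2ox.

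Type 2C protein phosphatases had a median ratio of 0.18 over 8 members, with 4 above 0 in every line and 2 below 0 (percentile 99.6, and 98.7 without CEPH). Of these only CEPH passed 2-fold in all 3 lines. After CEPH, EGR1 differed most among those higher, at 0.51 ± 0.33, followed by EGR3 at 0.23 ± 0.18, while POL, which acts in stem cell maintenance, was at -0.30 ± 0.09. The list's median was 0.32 on the array labelled CEPD1ox, 0.04 in CEPD2ox and 0.16 in CEPDL2ox. Without the array labelled CEPD1ox the percentile was 93.1 and the median ratio 0.11. Auxin response genes had a median ratio of 0.32 over 6 members (percentile 99.99), with 3 above 0 in every line and 0 past 2-fold in all 3. IAA29 had a mean ratio of 0.67 ± 0.43 from a WT signal of 2.29, below the filter value, the auxin-conjugating enzyme genes GH3.3 and GH3.5 were at 0.33 ± 0.55 and 0.32 ± 0.29, and LBD29, a regulator of lateral root formation, was at 0.31 ± 0.14. The median was 0.31 on the array labelled CEPD1ox, -0.02 in CEPD2ox and 0.45 in CEPDL2ox, and without CEPDL2ox the percentile was 95.6. Lists also stood apart when another array was set against the rest. For auxin response this was so of CEPDL2ox (percentile 100.0) and CEPD2ox (0.17), for the glutaredoxins of CEPD2ox (97.6) and CEPDL2ox (99.8), and for the phosphatases of the array labelled CEPD1ox (99.9). It was also so for iron deficiency of CEPDL2ox (98.2). The CEPD family was past the bounds for the array labelled CEPD1ox (0.04) and CEPD2ox (1.53), where overexpressed genes of the list again enter the comparison. Leaving the CEPD family aside, a percentile past the bounds is therefore not particular to the comparison with WT.

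The NRT1/NPF transporters, nitrate response regulators and iron deficiency genes that could be read did not stand apart in the mean of the 3 lines against WT. Only 6 of 15, 4 of 20 and 5 of 22 members of these lists had a named row. The other members were not read, so these values do not show how the whole lists behaved. NRT1/NPF transporters had a median ratio of -0.14 over 6 members (percentile 5.6), with 2 below 0 in every line and 0 past 2-fold in all 3. NPF6.2 had a mean ratio of -0.24 ± 0.22, NPF6.4 one of -0.16 ± 0.29, NPF3.1 -0.14 ± 0.30 and NPF2.7 -0.14 ± 0.11. Nitrate response regulators had a median of -0.08 over 4 members (percentile 12.4). This median was -0.03 without the array labelled CEPD1ox, -0.02 without CEPD2ox and -0.14 without CEPDL2ox. NRG2, which takes part in nitrate signalling, was at -0.16 ± 0.02, and the repressors HHO1, HHO2 and HHO3 were at -0.09 ± 0.29, -0.07 ± 0.10 and 0.08 ± 0.09. Iron deficiency genes had a median of 0.12 over 5 members (percentile 88.8), with S8H at 0.45 ± 0.83, IMA2 at 0.38 ± 0.19, PYE at 0.12 ± 0.22 and BHLH101 at -0.25 ± 0.08. Their median was 0.02 without the array labelled CEPD1ox, 0.24 without CEPD2ox and 0.02 without CEPDL2ox. The sign of 1 iron deficiency member turned under each other normalization. No sign turned in the other lists that had a percentile. Lists with fewer members were not checked for this.

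In another 12 lists, 1 or 2 members passed the filter, too few for a percentile. Of 20 photosynthesis genes, 2 had a named row, and both passed the filter. PRK is given above, and RCA, the Rubisco activase, was at -0.47 ± 0.26, past 2-fold in no line. The heat shock gene HSP15.7 was at -0.84 ± 0.41, with signals below the filter value in the lines. The dehydration genes KIN2 and KIN1 were at -0.48 ± 0.01 and 0.24 ± 0.21, the latter from a WT signal below the filter value. The detoxification gene GSTU25 was at 0.24 ± 0.27, and ZAT10, of the touch, wounding and cold list, at 0.44 ± 0.40. The CEP peptide genes CEP4 and CEP9 were at -0.25 ± 0.34 and 0.13 ± 0.49. The root hair expansins EXPA18 and EXPA7 were at 0.13 ± 0.25 and 0.11 ± 0.12, and the sulfate starvation genes BGLU28 and SDI2 at 0.12 ± 0.35 and 0.00 ± 0.30. CITF1 (copper deficiency), AUR1 (cell division) and GI (circadian clock) had mean ratios of 0.02, -0.09 and 0.00. The reference genes TIP41L and UBC21 were at 0.17 ± 0.09 and -0.11 ± 0.17. The other 13 lists had no member past the filter. In 9 of them no member had a named row, so the signals of their genes were not read. In the rest, NRT2.5, ARR15, ARR16, PDF1.2 and DFR had a named row and lay below the filter value. Those with such a row were high-affinity nitrate transport, cytokinin, jasmonate and flavonoids. Those without were nitrate assimilation, nitrogen compound uptake (ammonium, urea and amino acids), phosphate starvation, endodermis and suberin, and vascular tissue. The same held for salicylic acid defence, glucosinolates, potassium transport and plasma membrane proton pumps.

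Between the lines, 41 genes differed at least 2-fold from both others on the array labelled CEPD1ox (26 higher, 15 lower), 38 in CEPD2ox (20 and 18) and 42 in CEPDL2ox (18 and 24). In CEPDL2ox, AT2G30670 was 3.92-fold and CEPH 3.59-fold higher than the mean of the other lines, and AT5G52390 was 2.95-fold higher. CCOAMT, a caffeoyl-CoA methyltransferase gene, was 2.91-fold lower there, AT1G68270 was 3.49-fold lower and AT4G00005 2.73-fold lower. In CEPD2ox, the MADS-box gene AGL19 was 4.07-fold lower than the mean of the other lines, AT2G29820 3.44-fold and the glycosyltransferase gene AT2G36970 3.22-fold. AT2G16535, AT4G03156 and AT2G03570 were 3.70-, 2.98- and 2.92-fold higher there. On the array labelled CEPD1ox, AT1G68270 was 4.18-fold higher, AT3G24850 3.13-fold and AT5G04120 3.00-fold. AT1G72645 was 3.97-fold lower there, the germin-like gene AT5G39120 2.94-fold and for the MADS-box gene AGL93 the log2 difference from the mean of the other lines was -1.43. In AT1G68270, AT3G24850, AT1G72645, AGL93, AT2G16535, AT4G03156, AT2G29820, AT2G36970 and AT4G00005 the lower side of the comparison lay below the filter value on at least 1 array, so these folds are limited by background. Each value rests on single arrays, and at a 3-fold threshold 1, 4 and 3 genes remained in the counts for the array labelled CEPD1ox, CEPD2ox and CEPDL2ox.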

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

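The tests in this part were chosen after the results they weigh were seen, except that the count with each array taken as the one apart was planned.

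Among the rows without a gene name, rows 13545469 and 13545557 were at least 16-fold higher in all 3 lines than in WT, which no named gene was. They were looked at because they lie outside the named genes that the comparisons used. The smallest of the 3 log2 differences from WT was 5.11 for the former and 5.38 for the latter, and the largest were 6.77 and 7.11, both on the array labelled CEPD1ox. Their signals were between 9.50 and 11.2 in the lines, at or above the 94.8th percentile of each line array, and 4.39 and 4.13 in WT. Sequence introduced with the transgenes of all 3 lines could give this pattern, but so could a plant transcript shared by the lines. The rows moved together, with at most 0.35 between their log2 differences, and their target was not analysed here, so these cannot be told apart.

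CEPD1 was near its WT level on the array labelled CEPD1ox. A swap with the CEPD2ox or CEPDL2ox array is argued against, since CEPD2 and CEPDL2 were each higher on their own array than on this one, by at least 2.19 (log2). RNA like that of the WT array is argued against by the 2 rows at least 16-fold above WT in CEPD2ox and CEPDL2ox. Their smaller difference from WT was 6.77 here, and no other row differed by more than 3.61 between these arrays. The rule for these rows uses the WT array but not this one, yet both rows were already known to be high here. A row that does not respond to its transcript may account for the CEPD1 level. CEPD1 lay at the 25.5th percentile of this array and stayed low on all 4, so no array shows whether the row responds, and this cannot be told apart from a line that overexpresses CEPD1 little or a sample from outside the series.

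The count of genes at least 2-fold apart from WT in all 3 lines may come from the spread between single arrays: with the overexpressed genes left out, 18 genes stood apart with WT as the array apart, and between 18 and 21 with each other array. The counts for the line arrays can also hold effects of the overexpressed genes, so they do not separate these from spread between single arrays. For CEPH, such spread cannot be told apart from an effect of the overexpressed genes, which the design names. The mean ratio of CEPH was 2.08 times the SD that its own spread between the lines gives for such a difference. This fell short of the bound used, the upper 2.5% point of the t distribution with 2 degrees of freedom. The spread of CEPH between the lines can itself hold differences between the lines. No other WT array was analysed here.

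AT1G68270 was higher than WT by 1.198 (log2) on the array labelled CEPD1ox and differed by -1.38 in CEPDL2ox, in opposite directions, with 1 array each. The difference was not tested. The signals of this gene in WT, CEPD2ox and CEPDL2ox, 2.34, 1.99 and 0.96, lay below the filter value. The difference in CEPDL2ox is thus between signals near background, which limits the reading of opposite directions.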

How the results depend on the processing

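The 64 counts and log2 ratios recomputed with the arrays shifted to the same median, quantile or cyclic loess normalization, the mean over the rows of a gene or, for counts, no filter stayed within 1.5 times the reported count, or within 1.5-fold of the reported ratio. The log2 ratio of CEPH lay between 1.78 and 1.83, 2.21 and 2.25, and 3.81 and 3.84 over the normalizations. No result other than the CEPD family list turned its direction. Counts moved with the threshold and the filter, which change by construction how many genes can pass. In the order CEPD1ox, CEPD2ox, CEPDL2ox, higher in all 3 lines, lower in all 3 lines, then each of the 3 lines apart from both others, they were 916, 784, 877, 58, 57, 277, 324 and 316 at 1.5-fold. They were 21, 18, 28, 3, 2, 1, 4 and 3 at 3-fold, and 34, 25, 52, 4, 3, 4, 13 and 12 with the filter at the median. Over all rows of the table, unnamed and repeated ones included, a setting chosen after the data were seen, they were 1797, 1775, 1697, 97, 119, 659, 599 and 637. With 1 line fewer required, genes higher in the remaining lines numbered 18 without CEPD1ox, 20 without CEPD2ox and 17 without CEPDL2ox, and genes lower numbered 13 without CEPD1ox, 14 without CEPD2ox and 15 without CEPDL2ox. Among gene lists, leaving out a line took these percentiles inside the bounds: 93.1 for type 2C phosphatases without CEPD1ox, 52.5 and 33.3 for the CEPD family without CEPD2ox and CEPDL2ox (the median turned from 0.65 to -0.05 in the latter case, where 1 overexpressed gene fewer counts), and 95.2 and 95.6 for the other class III glutaredoxins and auxin response without CEPDL2ox. Apart from the lines left out, the cause was not tested. Means over members, unmatched random lists, no filter, quantile or loess normalization moved no list across the bounds, nor did leaving out the overexpressed genes and CEPH, added later and not run for the CEPD family. Low signal limits the counts: the median SD between lines was 0.28 below a log2 signal of 3 and 0.09 at 7 or above. The change of pseudocount planned for linear values was not run.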

Other observations

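AT2G30670 and AT2G30660 differed between the lines in the same order as CEPH for CEPD2ox and CEPDL2ox. Their log2 ratios to WT were 3.39 and 2.28 in CEPDL2ox against 1.46 and 0.99 in CEPD2ox. CEPH had 3.84 in CEPDL2ox and 2.21 in CEPD2ox. Each line has 1 array, and the order was not tested. CEPH and AT2G30670 were named for being higher in CEPDL2ox than in both other lines, so for them this order follows from the choice. AT2G30660 was also at least 2-fold higher there, at 7.47 against 6.17 on the array labelled CEPD1ox and 6.18 in CEPD2ox. All 18 genes counted as higher in CEPDL2ox than in both other lines have this order. The order therefore does not set these genes apart from the others.

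Of the 20927 rows without a gene name, 87 were at least 2-fold higher in all 3 lines and 108 lower. These hold 49 distinct sets of 4 values in each direction, since rows can repeat each other. Of all rows, 7138 shared all 4 values with another row, exactly as deposited and with no tolerance, and 6979 of these had no gene name. Over all rows, repeats included, 216 stood apart on the WT array, against 373 on the array labelled CEPD1ox, 322 on CEPD2ox and 345 on CEPDL2ox.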
